A study of Mus musculus with 2 samples.

How the data were processed

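H3K27me3 was measured by chromatin immunoprecipitation and sequencing in 2 biological replicates of the MEL cell line, which form 1 group. Group and replicate number were taken from the labels. Nothing in the sources says whether the replicates came from separate cultures, so the spread between them may be partly technical.

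Per the deposited text descriptions, the peaks of each replicate were called on its own mm10 alignments against 1 control alignment that both replicates share, the pooled list was called on the alignments of both replicates together, and the replicated list was derived from those 3 lists. Every one of the 38300 replicated peaks had the exact coordinates of a pooled peak, and 54.9% of the pooled peaks were kept. The rule for keeping them, the aligner and the peak caller are not given in the sources used here. How the mm9 list was made is not stated either. The authors' signal value of each peak is a score whose definition is not stated. It had been taken for a fold value when the comparisons were planned, and it was used to rank or filter peaks within a list, to correlate the strength of overlapping peaks between replicates, and to match peaks in a test on chromosome 11. The authors also deposited a −log10 p-value and a −log10 q-value for each peak. The mm10 lists admit weak peaks: −log10 q reached 2 in 30.8% of the peaks of replicate 1, 12.0% of those of replicate 2, 6.05% of the pooled peaks and 10.9% of the replicated peaks, and in all 40712 peaks of the mm9 list. The lists hold no read counts, so depth per replicate is unknown and no value could be given a counting interval from reads. The narrow peaks, with a median width of 182 bp in each replicate, split broad domains, and a base outside a peak is not shown to lack the mark.

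The reference was GRCm38, the build that mm10 names, with GENCODE mouse release 21 genes and the NCBI sequence. Every mm10 peak lay within the chromosome lengths of the reference. Peaks on chromosomes 1 to 19, X and Y were used. Coordinates of mm9 and mm10 were never mixed, and the mm9 list was compared per chromosome, by covered share and peaks per Mb. For the mm9 list the end of the last peak on a chromosome stood in for its length. Gene symbols given more than once kept their longest gene, which left 21911 protein-coding genes. A gene was called marked where a peak overlapped the 1 kb on either side of its start by at least 1 bp. The start was the outermost 5' end of the annotated gene, so promoters further inside a gene did not enter these counts.

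Covered length was taken from the union of peaks. Overlaps of lists, annotation classes and gene lists were compared with 1000 circular shifts of the peaks within each chromosome, which keep widths and clustering. Annotation classes were assigned in the order promoter, exon, intron and intergenic. The 23 gene lists were fixed before the data were examined, as were the tests, the alternatives and the rule for naming genes. The share of marked promoters in each list was compared with all other protein-coding genes by a two-sided Fisher's exact test with Benjamini-Hochberg adjustment over the 23 lists. That test treats neighbouring genes as independent, which the circular shifts do not. Intervals of shares of genes are exact Clopper-Pearson 95% intervals. Correlations over chromosomes were tested with 100000 permutations. Symbols without a protein-coding gene in the annotation, such as Ahsp, Meg3 and Kcnq1ot1, were left out of their lists.

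Named genes are up to 4 marked members of each list with the most bases covered within 5 kb of the gene start, the 10 genes of the genome with the most such bases, the protein-coding genes in the 10 longest domains, the marked erythroid, housekeeping and Polycomb genes, and the 10 genes marked in 1 replicate only with the highest signal value. Some genes that the rule selects are not reported here. Genes named outside this rule are said to be so.

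The alternatives were a −log10 q of at least 2, the upper 50% of replicated peaks by signal value, the pooled list, each replicate's own list, 50% of a peak covered in place of 1 bp, equal numbers of the strongest peaks, peaks joined within 3 kb, random placement with bedtools, promoters of 2.5 kb on each side, 500 bp of the promoter covered, matching on promoter GC in 10 bins with a Mantel-Haenszel test, circular shifts in place of Fisher's exact test, other joining distances, and peaks per Mb. The random placement used 100 draws, excluded the start of each chromosome, where the assembly holds no sequence, and left out the lone peak on chromosome Y. Gene-body coverage was added after the promoter results were seen. The Mantel-Haenszel test is an approximation that is weak where few marked genes are expected, as in most of the lists.

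The code was tested on simulated data. Peaks placed with an overlap of 40% were measured at 40.7%, and of 3 lists given a peak at 30% of their promoters 3 were called, with 0 of 20 other lists called. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6, bedtools 2.31.1 and matplotlib 3.10.9 were used.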

Results

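Histone H3 trimethylated at lysine 27 (H3K27me3), a mark laid down by Polycomb repressive complexes and found over silent developmental genes, was mapped by chromatin immunoprecipitation and sequencing in MEL cells. MEL is a mouse erythroleukaemia line, used as a mouse counterpart of a human leukaemia line. The series holds 1 group of 2 biological replicates and no other condition, so the comparisons are between replicates and between regions of the genome. Each replicate has its own list of peaks, and the authors also deposited a list called on both replicates together (the pooled list), a subset of it that they named replicated, and an older list on the mm9 build. Replicate 1 held 70905 peaks covering 16.1 Mb, and replicate 2 held 106999 peaks covering 23.9 Mb. The replicated list held 38300 peaks with a median width of 278 bp, which covered 13.0 Mb or 0.477% of the mm10 genome. Read depth is unknown, because the lists carry no read counts. All positions are on mm10 unless stated otherwise.

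Long stretches of H3K27me3 lay beside and within the HoxC cluster, a row of homeobox genes that set position along the body axis. When replicated peaks within 3 kb of each other were joined, the longest domain spanned 85873 bp (chromosome 15, 102777426 to 102863298), with 57.0% of its bases covered in the replicated list, 48.3% in replicate 1 and 54.6% in replicate 2. It held no protein-coding gene. The long non-coding RNA gene Gm36560 (102797495 to 102819544) lay inside it. This domain was not the longest in every analysis: among replicate 1's own peaks the longest measured 65553 bp and lay around Hoxc13 (102867520 to 102933072), and with replicated peaks joined within 10 kb it lay elsewhere (chromosome 9, 106915005 to 107139854). The next domain at 3 kb, of 63736 bp (102867520 to 102931255), held all of Hoxc13 and had 38.7% of its bases covered in replicate 1 and 47.6% in replicate 2. Inside the cluster the peaks ran past Hoxc13, Hoxc12 and Hoxc11 and ended before Hoxc10, which starts at 102966796. They left gaps, and replicated peaks covered no base of the bodies of Hoxc12 and Hoxc11. The last peak of the cluster ended at 102964552 in replicate 1, at 102964961 in replicate 2 and at 102964327 in the replicated list. From there to the end of Hoxc4 at 103036852 none of these lists held a peak, a border that was singled out after its values were seen.

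**Figure D1:**
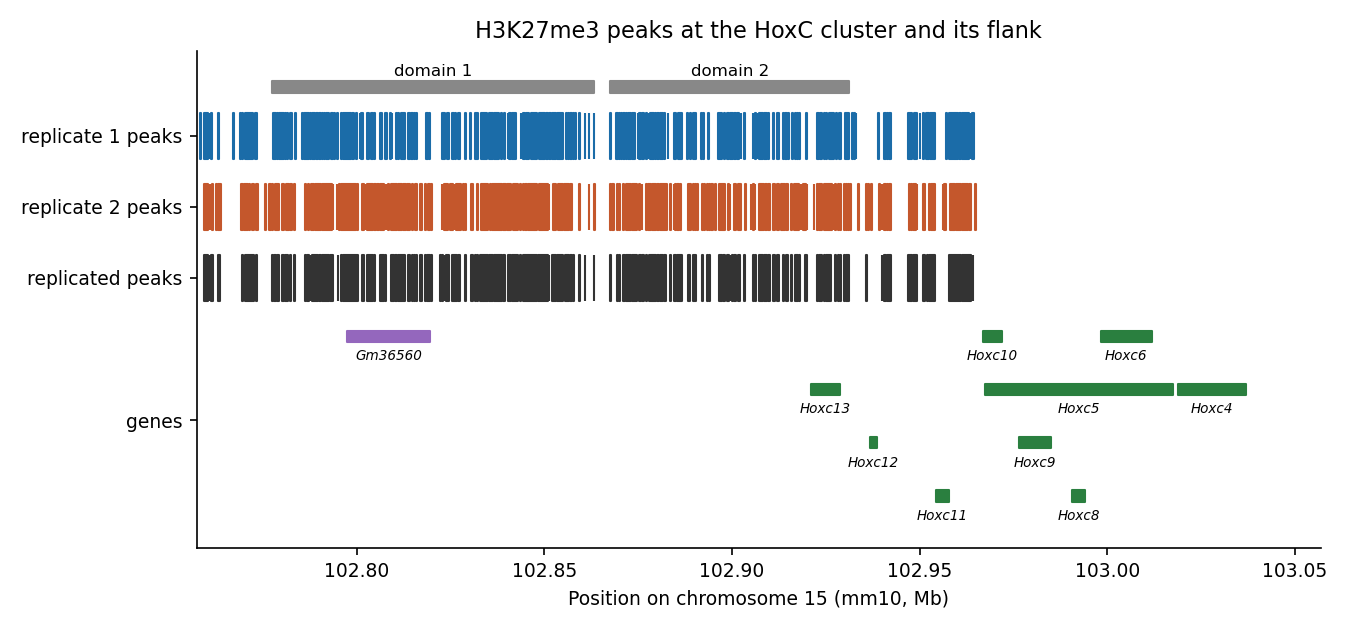
Peaks of replicate 1, replicate 2 and the replicated list along chromosome 15 (horizontal axis, mm10 position in Mb), with the 2 longest domains as grey bars, protein-coding genes in green and the non-coding gene Gm36560 in purple. Peaks of all 3 lists lie, with gaps, along the flank and the end of the cluster that holds Hoxc13, Hoxc12 and Hoxc11, and stop before Hoxc10.

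The 4 Hox clusters differed in coverage. Peaks covered 13.7% of HoxC in the replicated list (chromosome 15, 102921103 to 103036852), 13.6% in replicate 1 and 14.1% in replicate 2. HoxB (chromosome 11, 96194316 to 96368256) was covered over 6.71% of its length, with 7.28% in replicate 1 and 12.2% in replicate 2. HoxD (chromosome 2, 74668310 to 74765142) was covered over 0.694%, with 1.04% and 1.45% in replicates 1 and 2. HoxA (chromosome 6, 52155590 to 52260880) held 0 peaks in the replicated list, the pooled list and both replicates' own lists. Of windows as long as HoxA, 78.7% held no replicated peak, so HoxA did not stand apart. Across windows of the same length tiled along the genome, the mean share covered was 0.494%. Of 22743 windows as long as HoxC, 100 were covered as much or more, and of 15132 windows as long as HoxB, 233 were. HoxB lies on chromosome 11, of which replicated peaks covered 1.86%, and its windows were not limited to that chromosome. Of the 27188 windows as long as HoxD, 3352 were covered as much or more, so HoxD did not stand apart from other windows. No test was attached to these shares.

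Other long domains lay over single genes or small groups of neighbouring genes. Tanc2, which encodes a scaffold protein of synapses, held a domain of 63241 bp inside the gene (chromosome 11, 105854755 to 105917995). Neo1, a receptor for netrins, held one of 53004 bp inside the gene (chromosome 9, 58905535 to 58958538). A domain of 52743 bp lay over Aldh1a2, an enzyme that makes retinoic acid (chromosome 9, 71243591 to 71296333). The Wnt receptor gene Fzd3 held a domain of 51122 bp (chromosome 14, 65208525 to 65259646). Otof, needed for transmission by hair cells of the inner ear, had 46933 bp that included its start (chromosome 5, 30417219 to 30464151). The end of Mpzl2, all of Mpzl3 and part of Jaml, neighbouring genes of cell adhesion proteins, lay in a domain of 44706 bp (chromosome 9, 45052376 to 45097081). The potassium channel gene Kcnn3 held 43298 bp (chromosome 3, 89618470 to 89661767). Each of these domains was covered in both replicates, with the lowest share 25.3% for Kcnn3 in replicate 1. The replicated list was derived in part from the lists of both replicates, so coverage in both is not separate support. In all there were 14456 domains, of which 7478 consisted of a lone peak and 504 reached 10 kb. The count of domains of 10 kb or more was 980 in replicate 1 and 1897 in replicate 2, and it depended on the joining distance, with 55 at 1 kb and 1940 at 10 kb.

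Around gene starts the densest marking was at Rarg, which encodes a retinoic acid receptor: 7672 bases within 5 kb of its start were covered by replicated peaks (7318 in replicate 1 and 7178 in replicate 2). Jaml had 7234 bases. Dpm3, part of an enzyme that supplies mannose for glycosylation, had 6487 bases and the hormone gene Rln1 6439 bases. Hes1, a repressor induced by Notch signalling, had 6348 bases (5704 and 5103 in replicates 1 and 2). The ammonium transporter gene Rhbg had 6301 bases and Ikzf4, of the Ikaros family of lymphocyte transcription factors, 6145 bases. The olfactory receptor genes Olfr1395 and Olfr282 had 6062 and 6052 bases. Each of these genes had a replicated peak within 1 kb of the gene start. Only the outermost annotated start was examined, as for Dpm3, annotated over 7722 bp, so these peaks are not shown to lie at promoters in use.

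Of 21911 protein-coding genes, 658 (3.0%) had a replicated peak within 1 kb of the start. Circular shifts of the peaks along each chromosome gave 530 such genes on average (95% of shifts between 459 and 607; two-sided permutation p = 0.0040, a comparison that was not planned). Replicate 1 marked 978 genes and replicate 2 marked 1375, and 689 genes were marked in both, against 61.4 if the lists were independent. Of the 658 genes with a replicated peak, 524 were marked in both replicates' own lists. Among genes marked in 1 replicate's list only, the peaks with the highest signal value lay at Itsn1, Prrg4, A930018P22Rik, Fgf2, Wfdc6a and Htr3b in replicate 1 and at Olfr331, 4921501E09Rik, Hagh and Slamf9 in replicate 2. At each of these 10 genes the other replicate still had peaks within 5 kb, from 352 bases at Fgf2 to 2689 bases at Hagh. The count of 658 fell to 129 with peaks whose −log10 q was 2 or more, and to 182 when 500 bp of the promoter had to be covered.

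Few of the gene lists differed from other genes in their share of marked promoters. Of 23 lists, 1 differed from the remaining genes after Benjamini-Hochberg adjustment: 1 of 330 vomeronasal receptor genes (Vmn2r83) was marked, or 0.303% (exact 95% interval 0.00767% to 1.68%), against 3.04% of other genes (Fisher's exact test, two-sided, adjusted p = 0.021). The list passed the threshold in 4 of 9 alternative analyses, and did not pass with promoters matched on GC content or with circular shifts, which keep neighbouring genes together. The share stayed low in both: the ratio was 0.134 matched on GC. In the shifts 5.74 genes were marked on average (95% of shifts between 1 and 13), against the 1 observed. No list passed the threshold for a higher share. By Fisher's exact test 5 lists had an unadjusted p under 0.05. With circular shifts 2 did and none passed after adjustment, and with GC matching 3 lists passed.

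The lists with the largest shares were of other blood lineages and of Hox genes, and none of them passed the test. Among T-cell and NK-cell genes 4 of 28 were marked, or 14.3% (exact 95% interval 4.03% to 32.7%; Fisher's exact test, adjusted p = 0.069). They were Tbx21, a transcription factor of type 1 helper T cells, with 2422 bases covered within 5 kb of its start, the co-receptor gene Cd4 with 1304, Ets1 with 566 and the interleukin 7 receptor gene Il7r with 224. Small counts of covered bases moved between lists, as for Il7r, with 568 bases in replicate 1 and 682 in replicate 2, and for Epx, with 384 and 1646. Among myeloid genes 4 of 34 were marked (11.8%, Fisher's exact test, adjusted p = 0.084): the lipopolysaccharide co-receptor Cd14 (3448 bases), the macrophage growth factor receptor Csf1r (1840), lysozyme Lyz2 (697) and eosinophil peroxidase Epx (587). Among Hox genes 5 of 39 were marked (12.8%, exact interval 4.30% to 27.4%, adjusted p = 0.068): Hoxc11 (3789 bases), Hoxc12 (1285), Hoxb3 (1121) and Hoxd11 (452) were the most covered, and Hoxb8 (183), outside the rule for naming genes, was the last. Among 1134 olfactory receptor genes 49 were marked (4.32%, exact interval 3.21% to 5.67%, adjusted p = 0.069), the most covered after Olfr1395 and Olfr282 being Olfr223 (5787 bases) and Olfr288 (3692). At the promoters of Hoxc12, Hoxd11 and Epx the list of replicate 2 had a peak and that of replicate 1 had none. Of 9 alternative analyses, Hox genes passed the threshold in 4, myeloid genes in 3, T-cell and NK-cell genes in 1 and olfactory receptor genes in 5. With circular shifts the ratios to chance were 3.39 for Hox, 4.91 for myeloid, 5.16 for T-cell and NK-cell and 1.53 for olfactory receptor genes, and none of these lists passed.

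Erythroid genes, the line's own lineage, and genes in constant use were marked at shares that the test did not set apart from other genes. Of 44 erythroid genes 1 was marked (2.27%, exact 95% interval 0.0575% to 12%), Slc4a1, the anion exchanger of the red cell membrane, with 2099 bases covered within 5 kb of its start. Of 30 housekeeping genes 1 was marked, the translation elongation factor gene Eef1a1 (813 bases). The annotated Eef1a1 gene spans 10703 bp and only its outermost start was examined, so the peak is not shown to lie at the promoter in use. None of 35 ribosomal protein genes, 32 Polycomb complex genes, 22 stem and progenitor genes, 20 cell-cycle inhibitors and tumour suppressors, 17 pluripotency genes or 56 clustered protocadherin genes was marked. The upper 95% bounds of these shares ran from 6.38% for protocadherins to 19.5% for pluripotency genes, so the lists could not show a shortfall against 3.0%. Among lists of developmental transcription factors other than Hox genes, 0 of 32 endoderm and epithelial factors were marked, 1 of 46 neural transcription factors (Neurog2, 1511 bases) and 1 of 49 mesoderm and muscle transcription factors (Meox1, 2636 bases). Of 45 signalling ligands 2 were marked (Dhh, 484 bases, and Bmp5, 287 bases). The remaining lists had 1 or 2 marked members each: Selp and F5 of 19 megakaryocyte and platelet genes, Col1a2 and Col1a1 of 20 fibroblast and matrix genes, Ddc and Mest of 31 imprinted genes, Syn1 and Slc17a7 of 40 neuronal channel and synapse genes, Pou2af1 of 19 B-cell genes and Robo4 of 18 endothelial genes. The promoters of Mest and Pou2af1 had no peak in the list of replicate 1. For each list of this paragraph the adjusted p of Fisher's exact test was 0.39 or above.

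**Figure D2:**
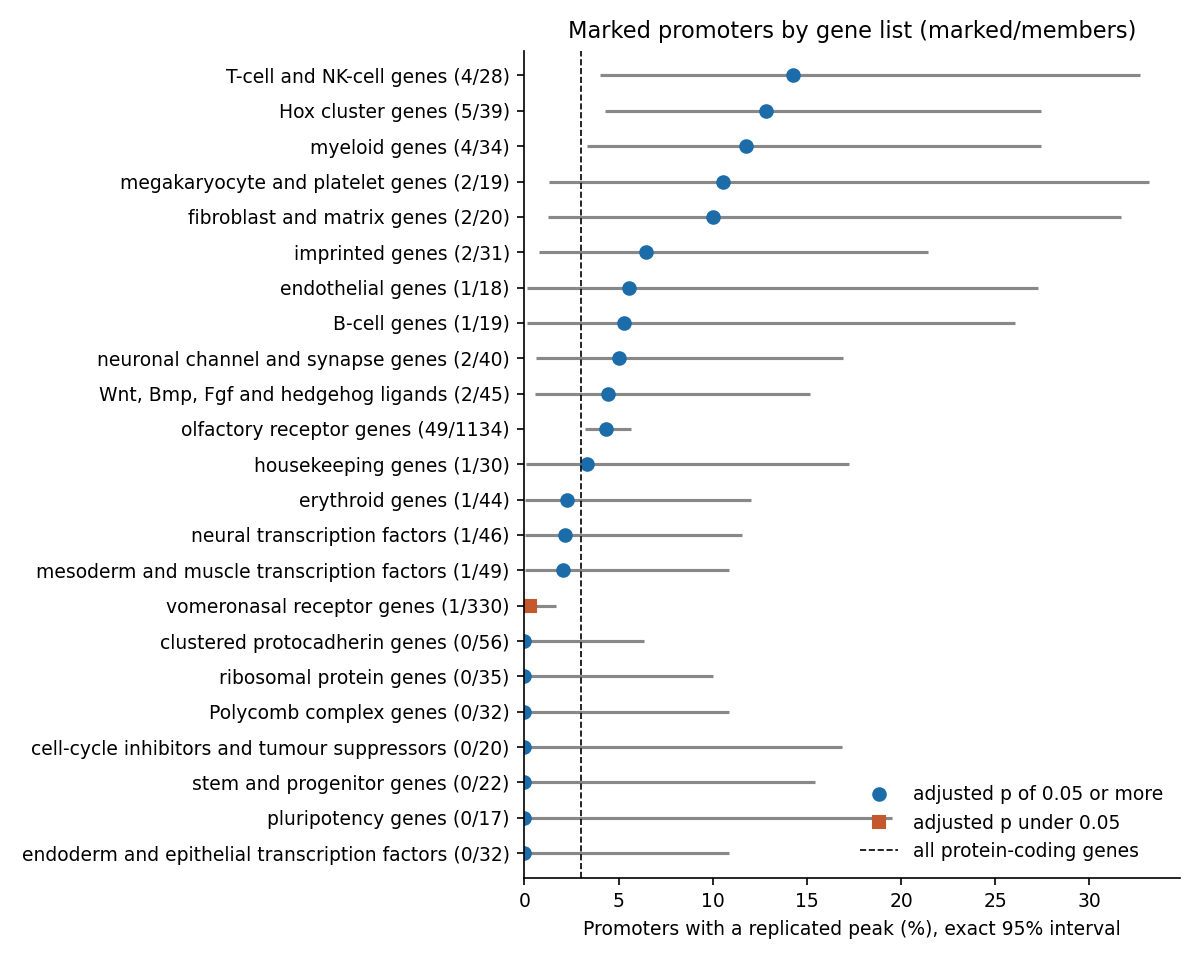
Share of promoters with a replicated peak in each of 23 gene lists (horizontal axis, percent; bars are exact 95% binomial intervals, and the dashed line marks all protein-coding genes at 3.0%). The list of vomeronasal receptor genes, the square at 0.303%, has an adjusted p under 0.05, and the other 22 lists do not.

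Peak bases were spread over exons, introns and intergenic sequence much as shifted peaks were, and the higher promoter share did not pass the threshold. Promoters, taken as 1 kb on each side of any protein-coding transcript start, held 3.30% of covered bases against 2.69% in circular shifts (95% of shifts between 2.28% and 3.19%; two-sided permutation p = 0.018, adjusted over 4 classes p = 0.072). Exons held 3.09% against 3.29%, introns 36.8% against 36.0% and intergenic sequence 56.8% against 58.0%, with a permutation p of 0.60 after adjustment for each. The promoter excess passed the threshold among peaks with −log10 q of 2 or more, where it was 1.51-fold (permutation test, adjusted p = 0.0080), and its adjusted p ranged from 0.0080 to 0.16 over the alternatives. It also passed in the upper 50% by signal value, in the pooled list and with promoters of 2.5 kb on each side, and did not in either replicate's own list. Coverage at the gene start was lower than upstream of it, and for GC-rich genes also lower than downstream. In the 500 bp after the start it was 0.326% for the 10996 genes in the upper 50% by promoter GC and 0.675% for the 10915 others, against 1.52% and 1.09% in the bin that starts 5 kb upstream and 0.939% and 0.757% in the bin that starts 5 kb downstream. For the genes of lower GC the downstream bins fell as low as 0.687%, close to the value at the start.

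**Figure D3:**
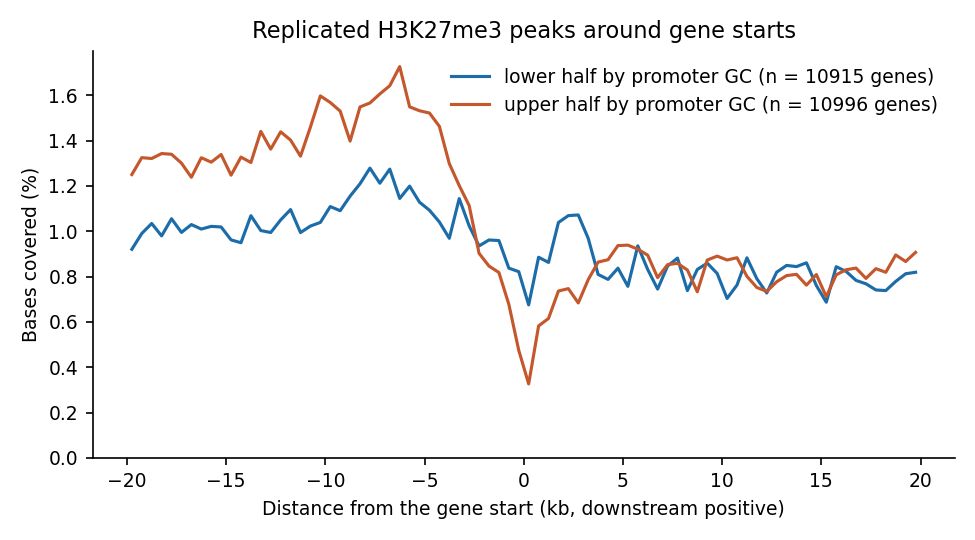
Percent of bases covered by replicated peaks (vertical axis) in bins of 500 bp by distance from the gene start (horizontal axis, kb), for genes in the upper and lower 50% by GC content of the promoter. Coverage of the GC-rich genes falls from 1.52% in the bin 5 kb upstream to 0.326% at the start.

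The replicates marked many of the same places. Of replicate 1's peaks 44.9% overlapped a peak of replicate 2 by at least 1 bp, against 2.21% in circular shifts, and of replicate 2's peaks 29.8% overlapped one of replicate 1, against 1.47%. The Jaccard index of covered bases was 15.8%, against 0.488% in shifts. Each one-sided permutation p was 0.0010, the smallest that 1000 shifts can give. Both replicates were called against the same control, and the shifts do not measure how much overlap a shared control alone would give. Overlap was highest among the strongest peaks: 32% of the weakest 10% of replicate 1's peaks by −log10 p and 73.2% of the strongest 10% had a partner, and in replicate 2 these shares were 19.6% and 59.1%. The share did not rise steadily in between, and the strongest peaks of replicate 1 were also wider, with a median of 310 bp against 148 bp for the weakest. Of the replicated peaks, 27732 (72.4%) overlapped both replicates' own lists. Across these peaks, which are not independent replicates, the signal values of the replicates had a Pearson's r of 0.229 and a Spearman's rho of 0.184. Among the 3985 with −log10 q of 2 or more r was -0.131 and rho -0.186. That selection is on the strength of both replicates together, which can by itself lower their correlation, by an amount that was not measured.

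Chromosome 11 carried the highest share of marked sequence. Replicated peaks covered 1.86% of it, against 0.873% of chromosome 19, 0.841% of chromosome 15, 0.815% of chromosome 9 and 0.667% of chromosome 2, the next in order. Chromosome 8 had 0.173% and chromosome X 0.220%. Both replicates had chromosome 11 highest, at 2.05% and 2.68%, and so did the mm9 list at 1.13%. Over the 21 chromosomes the shares of replicates 1 and 2 had a Pearson's r of 0.996 and a Spearman's rho of 0.986, and those of the mm9 list and the replicated list an r of 0.979 and a rho of 0.913. Each permutation p, raw and adjusted over 2 comparisons, was 1e-05, the smallest that 100000 permutations can give. The mm9 list belongs to the same series, so its agreement with the replicated list is not independent support. Without chromosomes 11 and 19, the 2 farthest from the median, r was 0.992 and 0.938.

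**Figure D4:**
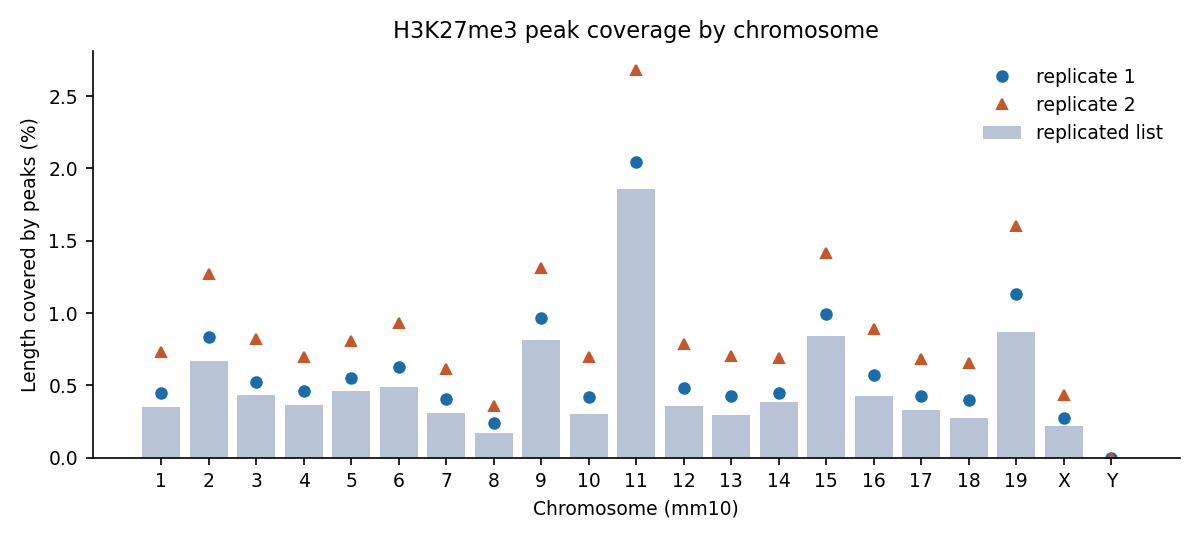
Share of each chromosome's length covered by peaks (vertical axis, percent) in the replicated list (bars), replicate 1 (circles) and replicate 2 (triangles). Chromosome 11 is the highest in each, at 1.86%, 2.05% and 2.68%.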

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

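The unplaced contig GL456367 lies outside the chromosomes used in the comparisons, and both replicates had peaks on it. Each replicate's list held 4 peaks there, the pooled list 3 and the replicated list 2. They are given because no comparison used them, and no explanation was tested.

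The tests in this part were chosen before their results were seen, except the mean differences by chromosome and the windows that hold a gene start, which were chosen after. The pattern most in need of a closer look is the coverage of chromosome 11, 1.86% against 0.873% for the next chromosome. In 1 Mb bins set against bins of other chromosomes with similar gene counts, the ratio of covered shares was still 2.93 (bootstrap 95% interval 2.22 to 3.71), above the bound set beforehand, which argues against gene density as the whole cause. The interval does not give the spread between chromosomes. Among the other chromosomes with replicated peaks the same ratio ran from 0.360 on chromosome 8 to 1.88 on chromosome 15. Extra copies of chromosome 11 in this cell line could raise the number of peaks that pass a threshold, and the median difference in −log10 p from other peaks in the same bin of signal value was 0. It was 0 on each of the 20 chromosomes with replicated peaks, although the mean difference ran to 0.171 on chromosome 11 and 0.219 on chromosome 15, so the median could not separate chromosomes and extra copies stay open. The design holds no second cell type, and no biological explanation was tested.

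Promoters rich in GC were less covered than their flanks even inside long domains. Among 69 genes with promoter GC of 55% or more, 7.82% of promoter bases and 21.8% of flanking bases were covered, and the promoter was the lower in 63 genes. Among 222 genes with lower promoter GC the shares were 17.3% and 19.7%, with the promoter lower in 139 genes and higher in 83. Loss of GC-rich sequence in library preparation or sequencing may contribute. It was examined in 1 kb windows inside long domains and over 5 kb from any transcript start. The domains of these windows were peaks joined within 10 kb, not within 3 kb, and had a minimum length set beforehand. Among these windows, coverage at GC of 55% or more was 0.559 times that at 40% to 45% (bootstrap 95% interval 0.420 to 0.697), 9.92% against 17.7%. Windows inside domains that held a gene start were 9.92% covered at GC of 55% to 60%, against 9.97% away from starts. At 55% or more the shares were 7.57% and 9.92%. The last contrast is not matched on GC: 57 of 122 windows with a start had GC of 60% or more, against 14 of 226 away from starts. The ratio lay between the bounds set beforehand for and against this explanation, so GC loss and a true gap at promoters cannot be told apart here.

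Many peaks of each replicate had no partner in the other. If weak peaks near the calling threshold were the whole cause, the strongest 10% of replicate 1's peaks by −log10 p were predicted to have a partner in over 90% of cases, and 73.2% did, against 44.9% of all its peaks. The share was higher among the strongest peaks, which were also wider, but stayed under the predicted level, which leaves open how much of the mismatch weak peaks may account for. Read depth is unknown for both replicates and was not tested.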

How the results depend on the processing

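The gene-body test was chosen after seeing the data, and the other alternatives were planned. No paired analysis was possible because there is 1 group. Overlap of the replicates and agreement of their strength need both replicates, so no replicate was left out there. The overlap between replicates stayed above chance under every alternative (the share of replicate 1's peaks ranged from 21.1% to 56.3%), and the correlations over chromosomes stayed past the threshold. Of the 61 genes that the rule selects, 34 had bases covered within 5 kb of the start with −log10 q of 2 or more. Over the alternatives, 171 values of these genes moved by more than the spread between replicates and 134 did not. Unknown depth limits the counts of peaks, domains and marked genes. Where no reason is given, the cause was not tested.

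Agreement of strength gave r = 0.275 and rho = 0.201 on −log10 p, and r = -0.131 and rho = -0.186 with −log10 q of 2 or more, a selection on pooled strength. The promoter excess in covered bases passed the threshold at 1.51-fold with −log10 q of 2 or more, 1.29 in the upper 50% by signal value, 1.19 in the pooled list and 1.45 with promoters of 2.5 kb on each side, where the intron ratio turned to 0.991. By peak midpoints the excess passed only with −log10 q of 2 or more and with promoters of 2.5 kb on each side. Marked genes numbered 978 to 1375 in single replicates, 129 with −log10 q of 2 or more, 425 in the upper 50%, 182 with 500 bp covered and 1309 with wide promoters.

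Gene lists past the threshold numbered 2 to 4 in single replicates, 0 in the upper 50%, 4 in the pooled list, 2 with wide promoters, 3 matched on GC, 0 with circular shifts and 0 by gene body. The ratio of the Hox share to that of other genes passed the threshold at 3.28 without replicate 1 (2.88 without replicate 2, not past it), 3.45 in the pooled list, 3.88 with wide promoters and 4.91 matched on GC. The myeloid ratio passed at 4.64 to 5.19 in single replicates and 3.96 in the pooled list, the T-cell and NK-cell ratio at 4.35 matched on GC, and the olfactory ratio at 1.44 without replicate 1 (1.30 without replicate 2, not past it), 2.78 with −log10 q of 2 or more, 1.41 in the pooled list, 2.52 with 500 bp covered and 1.94 matched on GC. The vomeronasal ratio lost its call at 0 with −log10 q of 2 or more and with 500 bp covered, 0.154 in the upper 50%, 0.134 matched on GC, 0.174 with circular shifts and 0.144 by gene body.

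Ratios that crossed 1 had no call in the main analysis and none in the setting where they crossed. The Hox and myeloid ratios were called above 1 in other settings, given before. With −log10 q of 2 or more they were 0 for Hox, myeloid, ligand, megakaryocyte, B-cell, endothelial, fibroblast and imprinted genes, and with 500 bp covered 0 for myeloid, ligand, megakaryocyte, B-cell, endothelial, fibroblast and imprinted genes and 2.46 for mesoderm factors. In the upper 50% they were 1.12 for neural factors, 1.05 for mesoderm factors, 1.17 for erythroid and 0 for B-cell genes. With wide promoters they were 1.09 for neural factors, 0.930 for endothelial, 0.837 for neuronal and 0.558 for housekeeping genes. In the pooled list they were 0.992 for ligands, 1.31 for pluripotency, 1.01 for erythroid and 0.743 for housekeeping genes. Between the lists without replicate 2 and without replicate 1 the ratio went from 0.457 to 1.30 for mesoderm factors, 0.700 to 1.5 for endoderm factors, 0.996 to 1.42 for ligands, 1.32 to 0.937 for pluripotency, 1.02 to 0.724 for erythroid, 2.25 to 0.796 for neuronal, 0.747 to 0.531 for housekeeping and 0.722 to 1.03 for imprinted genes. The erythroid ratio was 1.00 with circular shifts. By gene body they were 1.98 for mesoderm factors, 5.34 for endoderm factors, 0.622 for neuronal and 0.0822 for housekeeping genes.

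HoxB coverage was 7.28% to 12.2% in single replicates, 1.67% with −log10 q of 2 or more, 4.27% in the upper 50% and 9.40% in the pooled list. HoxC coverage was 13.6% to 14.1% in single replicates, 5.33% with −log10 q of 2 or more, 9.04% in the upper 50% and 15.6% in the pooled list. HoxD coverage was 1.04% to 1.45% in single replicates and 0 with −log10 q of 2 or more. Domains numbered 24279 to 33561 in single replicates and 8922 joined within 10 kb. Those of 10 kb or more numbered 980 to 1897 in single replicates, 55 joined within 1 kb and 1940 within 10 kb, where the longest measured 27226 and 224850 bp.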

Other observations

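The test of gene bodies and the choice of the genes named in this part were made after the promoter results had been seen. Over whole gene bodies, the mark lay on some developmental and lineage genes, several of which had no marked promoter. Peaks covered 24.2% of the Wnt ligand gene Wnt9a (21.1% in replicate 1 and 27.4% in replicate 2) and 20.8% of Wnt3a near it (21.2% and 23.3%), both on chromosome 11. They covered 37.0% of Hoxc13 (37.9% and 47.0%), 17.4% of Kdr, the main receptor for vascular endothelial growth factor (18.7% and 22.5%), 15.6% of the integrin gene Itgam of myeloid cells (15.2% and 18.8%) and 20.0% of the imprinted gene Asb4 (19.2% and 18.4%). Among lymphoid genes, 31.8% of Cd4 (27.4% and 35.5%) and 36.2% of Ikzf3, a lymphocyte transcription factor of the Ikaros family (37.4% and 37.1%), were covered, and both had a marked promoter. Of all 21911 protein-coding genes 445 reached 10%, so a short list with 0 such genes, such as the 44 erythroid genes, is not set apart by it.

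Summed over lists, 3.29% of the bodies of 32 endoderm and epithelial transcription factors was covered against 0.617% in circular shifts (two-sided permutation p = 0.014, adjusted p = 0.15), and 2.53% of 45 signalling ligands against 0.605% (p = 0.012, adjusted p = 0.15). In the same permutation test imprinted genes had 2.13% against 0.546% (p = 0.026, adjusted p = 0.15) and T-cell and NK-cell genes 2.05% against 0.539% (p = 0.034, adjusted p = 0.16). Vomeronasal receptor genes had 0.0515% against 0.356% (permutation p = 0.026, adjusted p = 0.15). None of the 23 lists passed the threshold after adjustment, and all protein-coding genes together had 0.524% against 0.513% (permutation p = 0.65).

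The mm9 list differed from the mm10 lists in its values. Its signal value exceeded 100 in 1831 peaks, against 0 peaks of either replicate, and 277 of its peaks were 1 bp wide, while the narrowest peak of the replicates measured 140 bp. Because coordinates of mm9 and mm10 were not mixed, the lists were compared by position only through covered share and peaks per Mb of each chromosome.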
